A study of Mus musculus with 4 samples.

How the data were processed

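RNA from whole duodenum of mice at postnatal day 5 was measured on 4 two-colour Agilent arrays. Each array held 1 animal whose Arx gene was deleted in the intestinal epithelium through villin-Cre, a Cre recombinase under the promoter of an epithelial gene, and 1 wild-type animal. Per the labels, mutants 5 and 6 were labelled with Cy5 on arrays 1 and 2 beside wild types 1 and 2 in Cy3, and mutants 7 and 8 were labelled with Cy3 on arrays 3 and 4 beside wild types 3 and 4 in Cy5. Each animal was hybridised on 1 array, so that the comparison rested on 4 mutant and 4 wild-type animals. Per the labels' protocols, total RNA was extracted with Trizol and passed a RIN limit. All 4 arrays lay on 1 slide and were scanned together per the file headers, so no slide or scan batch could be tested. The pairing of a mutant with a wild type on an array was kept by working on the ratio within each array.

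Per the file headers, the deposited scanner files came from Agilent Feature Extraction 11.5.1.1 with array design 026655 and probe coordinates on the mouse build mm9. The intensity columns used were the mean spot intensity and the median local background in each colour, which per the file headers were not yet background-subtracted or normalised. The authors' files also held Agilent's processed intensity, which per the file headers was background-subtracted with spatial detrending and dye-normalised by a linear and lowess step, and this served as an alternative. A table of the authors' own comparison was deposited as well. Its signed fold change and its false discovery rate in percent were treated as a score, and its adjusted p-value was taken as deposited by the authors, whose method is not given in the sources used here. The direction of the authors' fold was read from its match to the scanner files. The 4 columns of values per hybridisation in that table carried names that matched no sample, and they were not used.

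Each array held 44397 spots, of which 1377 were control spots. The remaining spots covered 39429 probes, 399 of them spotted 10 times. Gene symbols were updated through the RefSeq accession for 28025 probes, 5734 probes kept the symbol in the file and 5670 had no symbol. Backgrounds were corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, and log ratios were normalised within each array by loess with control spots at weight 0. No scaling between arrays was applied. Control spots and spots marked as non-uniform or population outliers by the scanner software were then left out, which removed 170 to 231 spots per array, and spots of a probe were averaged. A probe was tested if it was well above background in at least 4 of the 8 channels, and 22830 probes were. A probe spotted several times counted as above background in a channel where at least a share of 0.5 of its spots did. Each gene was represented by its tested probe with the highest mean intensity, which gave 17911 features, 15578 with a symbol and 2333 probes without one. Of 4037 genes with several tested probes, 2924 had probes with the same sign.

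The scanner's saturation mark missed most spots at the ceiling of the intensity scale: 734 spot channels carried it and 2074 more lay at the ceiling. A spot therefore counted as saturated if marked or within 0.1% of the channel's highest mean signal, a rule set after the files were seen. Saturated spots were kept. The 130 tested genes saturated in all 8 channels have no readable ratio, were not called and are given no fold, and 16 called genes were saturated in some channel. A gene saturated, or not well above background, in all 4 animals of a genotype has a bound only, written as "at least". The bound sets the mean of the bright genotype against the dim genotype's mean of the higher of its own signal and the lowest signal among probes above background, after loess and Aquantile. Where the other genotype was also saturated in some animal, no bound is given, and such a gene was left out of the alternatives. The median of a list on an array leaves out spots saturated in either channel of that array, while the list tests and the medians over all arrays keep them, a choice made after the values were seen.

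The mutant and the wild type were compared with limma's lmFit and eBayes on the log2 ratios, with genotype coded by dye orientation and an intercept for gene-specific dye effects, 2 residual degrees of freedom and 2.412 prior degrees of freedom. Positive log2 values mean higher in the mutant. The two-sided p-values were adjusted by Benjamini-Hochberg over all tested features, with a threshold of 0.05, and every adjusted p for a gene in the report is limma's. Confidence intervals are 95% intervals from the same fit, and SDs are over the 4 array ratios. Because the dye intercept absorbs any difference between arrays 1 and 2 on one side and arrays 3 and 4 on the other, the intervals and p-values rest on the spread between the 2 arrays of each orientation, while the SD holds both.

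The 29 gene lists of intestinal cell types, metabolic pathways, cell states and other tissues that a dissected duodenum can hold were fixed before the data were examined. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 29 lists, and again with an estimated correlation. The function fry (statmod 1.5.0 installed) tested whether a list's genes moved on balance in one direction, and its mixed form whether they changed in either direction. Neither form compares a list with other genes. The named genes followed a rule fixed at the same time: Arx, every measured enteroendocrine hormone, the 12 largest rises and 12 largest falls among genes with a symbol past adjusted p 0.05 with the same sign on all 4 arrays, and 2 to 4 members with the smallest p from each other list. Symbols that are only clone or model names were counted and not named. A few further members are named in counts or as markers, chosen after their values were seen. Sex-linked genes are given as values only. Of all genes, 3 stood in more than 1 list.

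The steps were tested on simulated data with 17887 genes and 20 simulations, each with 200 changed genes. The genotype test called 62.7% of genes changed 1.5-fold, 94.8% of those changed 2-fold, 99.4% of those changed 4-fold and 0.0939% of unchanged genes. Lists of 15 genes shifted 1.5-fold were called in 20 of 20 simulations by camera and by fry, and unshifted lists in 0. The simulated genes varied independently, so these shares do not cover correlated genes.

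Alternatives changed the background correction, the normalisation within and between arrays, the filter on dim probes, the dye term, the probe chosen per gene, the outlier spots, the variance prior, array weights, a separate-channel fit, the threshold and the array left out. Files were read with the R package data.table (version 1.17.8), and plots were drawn with matplotlib. Between 24143 and 27465 spots per channel were well above background, with median spot signals of 80.0 to 98.8 before background correction and median local backgrounds of 27 to 45. The number of arrays limits the precision.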

Results

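Gene expression in the whole duodenum, the first part of the small intestine, was compared between 4 mice lacking Arx in the intestinal epithelium and 4 wild-type littermates, all at postnatal day 5. Arx encodes a homeobox transcription factor known for its part in specifying hormone-producing enteroendocrine cells, a small population scattered in the gut epithelium. Each of the 4 arrays paired a mutant with a wild-type animal, with the mutant in Cy5 on arrays 1 and 2 and in Cy3 on arrays 3 and 4. Between 56.1% and 63.8% of the spots in a channel were well above background. Across genes, which are not independent replicates, the mutant to wild-type log2 ratios of any 2 arrays correlated with r from 0.25 (arrays 1 and 4) to 0.65 (arrays 2 and 4).

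The Arx probe was lower in the mutant on all 4 arrays. Its mean log2 ratio was -0.70 ± 0.17 (SD, n = 4 arrays), 1.62-fold lower, with a 95% confidence interval from -0.94 to -0.46 and an adjusted p of 0.0432 in limma. The array holds 1 Arx probe of 60 bases, at positions 90543615 to 90543674 of chromosome X on mm9, which starts at base 2649 of the transcript. It was well above background in 3 of 4 mutants and 4 of 4 wild types. The labels do not say which part of the gene was deleted, and the whole duodenum also holds cells without villin-Cre, so the probe does not check the genotype labels. With Agilent's processed signals the log2 ratio was -1.78 (3.43-fold lower, adjusted p = 0.0499), and the call was lost when any 1 array was left out (adjusted p from 0.0804 to 0.268).

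The question of which hormones change without Arx was addressed with 12 enteroendocrine hormone genes (for serotonin, its synthesising enzyme). Cck, encoding cholecystokinin, fell 17.4-fold (log2 ratio -4.12 ± 0.084, SD, n = 4 arrays, interval -4.28 to -3.96, adjusted p = 0.00133). Gip, encoding the glucose-dependent insulinotropic polypeptide, fell 10.1-fold (-3.33 ± 0.065, interval -3.50 to -3.16, adjusted p = 0.0021). Nts, encoding neurotensin, fell 4.27-fold (-2.10 ± 0.74, interval -2.58 to -1.61, adjusted p = 0.0421). Sst, encoding somatostatin, rose 3.33-fold (1.73 ± 0.13, interval 1.54 to 1.92, adjusted p = 0.0208). The direction was the same on all 4 arrays for each of these 4 genes. Cck was saturated in 2 of 4 wild types and Nts was above background in only 2 of 4 mutants, so both falls are understated. The fall of Nts depended on the processing: 6.53-fold with a normexp offset of 10 (log2 ratio -2.71) and 20.4-fold with Agilent's processed signals (-4.35, adjusted p = 0.0499).

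The other 8 hormone genes did not pass the threshold over all genes. Secretin (Sct) had a log2 ratio of -0.85 ± 0.43 and was lower on 4 of 4 arrays (adjusted p = 0.0692), and ghrelin (Ghrl) had 0.27 ± 0.087 and was higher on 4 of 4 (adjusted p = 0.0711). Values were 0.33 for Tac1 (adjusted p = 0.0835), 0.47 for Pyy (adjusted p = 0.264) and -0.13 for Tph1 (adjusted p = 0.465). Gastrin, Gast, which the stomach also makes, had a mean of -0.15 ± 1.01 (adjusted p = 0.572), with -0.86, -1.05, 0.19 and 1.12 on arrays 1 to 4, where the medians of the stomach list were -0.83, -0.46, 2.77 and 3.37. Insl5 had a mean of -1.09 ± 1.47 (adjusted p = 0.279), made of 0.16 and 0.21 on arrays 1 and 3 and of -2.28 and -2.43 on arrays 2 and 4. Proglucagon, Gcg, had a mean of -0.06 ± 1.47 (adjusted p = 0.887), with 1.096 and 1.121 on arrays 1 and 2 and with -0.51 and -1.94 on arrays 3 and 4. On the same arrays the median of the pancreatic islet list, whose alpha cells also express Gcg, was 1.497, 1.607, 0.96 and -0.06. Sst had 1.76, 1.55, 1.86 and 1.77 on arrays 1 to 4 and so followed neither the islet nor the stomach medians. Which cells of the samples its rise came from was not tested. Adjusted over the list alone, 3 hormone genes were higher and 4 lower. Against all other genes the list was not past the threshold in camera (adjusted p = 0.189, median log2 ratio -0.14, mean -0.75). Fry, which does not compare the list with other genes, gave an adjusted p of 0.0291 for a net downward move and 0.00063 for change in either direction.

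**Figure D1:**
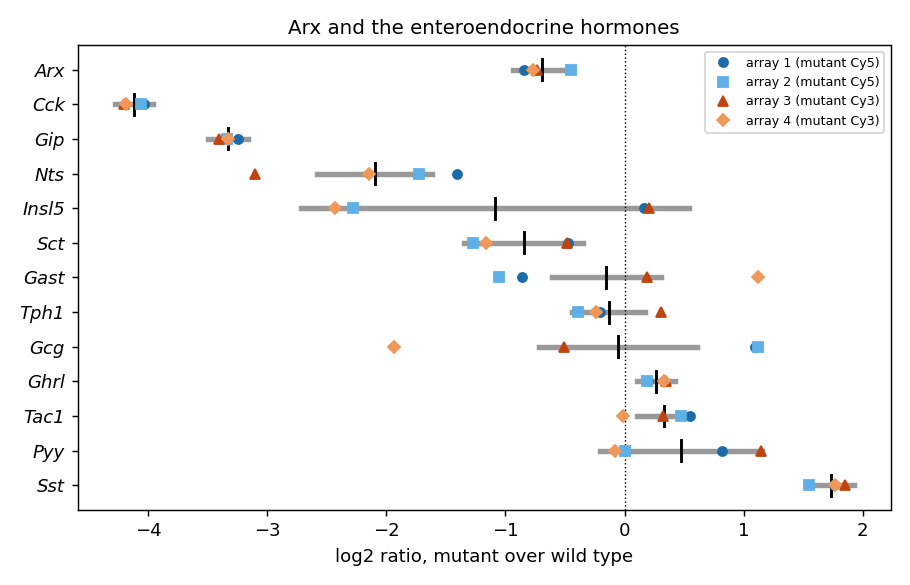
Log2 ratio of mutant over wild type for the Arx probe and 12 enteroendocrine hormone genes. Points are the 4 arrays, black ticks the mean and grey bars the 95% confidence interval from limma. Cck, Gip and Nts lie below 0 and Sst above 0 on all 4 arrays, while Gcg, Gast and Insl5 take both signs.

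The probes of the changed hormone genes lie on mm9 at chromosome 9, 121398943 to 121399002 (Cck), chromosome 11, 95886745 to 95887966 (Gip, where the coordinates span more than the probe's length), chromosome 10, 101944967 to 101945026 (Nts) and chromosome 16, 23889776 to 23889835 (Sst). Exon and untranslated-region annotation of mm9 was not used here.

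Genes of hormone granules and peptide processing moved in both directions. Of 16 members, 4 rose and 2 fell over all genes, and 6 were higher and 4 lower adjusted over the list alone. Pcsk2, a prohormone convertase, rose 2.21-fold (1.14 ± 0.11, adjusted p = 0.0421), and Scg5, a chaperone of that convertase, rose 1.56-fold (adjusted p = 0.0432). The islet list also shifted up, and which cells gave the rises of Pcsk2 and Scg5 was not tested. Chgb, the granule protein chromogranin B, fell 1.93-fold (-0.95 ± 0.43, adjusted p = 0.0421), and the vesicular monoamine transporter Slc18a1 fell 2.06-fold (-1.04 ± 0.22, adjusted p = 0.0421). The list as a whole was not past the threshold (camera adjusted p = 0.487).

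Of the 22 endocrine transcription factors, 14 were tested, and Arx was the 1 past the threshold over all genes. Adjusted over the list alone, 2 were higher and 1 lower. Foxa2 had a log2 ratio of 0.64 ± 0.25 (adjusted p = 0.0547), Hhex 0.50 ± 0.21 (adjusted p = 0.0547) and Insm1 0.24 ± 0.16 (adjusted p = 0.0904). Insm1 was near 0 with median centring in place of loess (-0.02). Neurod1, Pax6 and Rfx6 were among the 8 members that were not tested because their probes were too rarely above background. Of 7 tested nutrient receptors and ion channels, 2 rose, the long-chain fatty acid receptor Ffar4 (0.60 ± 0.47) and the sulfonylurea receptor Abcc8 (0.63 ± 0.13), and none fell. Ffar4 had 0.24 and 0.15 on arrays 1 and 2 and 0.97 and 1.05 on arrays 3 and 4, where the stomach list was also high. Abcc8 had 0.82, 0.55, 0.64 and 0.52 on arrays 1 to 4, and which cells its rise came from was not tested. Cckar, a receptor for cholecystokinin, had 1.15 ± 0.63 (adjusted p = 0.0725), with 0.31, 1.80, 1.39 and 1.102 on arrays 1 to 4. The medians of the pancreatic acinar list ran alike there, with 0.15, 1.42, 1.32 and 0.85. The somatostatin receptor Sstr5 had -0.22 ± 0.11 (adjusted p = 0.116). Adjusted over the list alone, 3 of the 7 were higher. Neither list was past the threshold (camera adjusted p = 0.189 and 0.155).

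Over all 17911 features, 850 passed the threshold, 329 higher and 521 lower in the mutant, and 825 of them had the same sign on all 4 arrays. Of the 850, 118 changed 2-fold or more, 66 higher and 52 lower. An unadjusted p under 0.05 was reached by 5932 features, where 896 are expected by chance. The calls lie close to the threshold of the test: 14, 5, 3 and 3 genes passed when array 1, 2, 3 or 4 was left out, Cck, Reg3b and Reg3g each time, and the fit without a dye term called 630. Of the 61 genes past the threshold that the naming rule took, 31 were called in every planned setting with 4 arrays. The interval of a gene rests on the spread within each dye orientation, so a gene such as Cyp4a10 can have a narrow interval while its ratios differ between orientations.

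Genes of the Reg family, secreted C-type lectins of the intestine and pancreas, had the largest rises. Reg2 rose 77.8-fold (6.28 ± 0.35, interval 5.91 to 6.66, adjusted p = 0.00295), Reg3b 53.3-fold (5.73 ± 0.38, interval 5.33 to 6.14, adjusted p = 0.00362), Reg3g 24.3-fold (4.602 ± 0.49, adjusted p = 0.00362), Reg3a 18.6-fold (4.21 ± 0.93, adjusted p = 0.0421) and Reg3d 6.29-fold (2.65 ± 0.42, adjusted p = 0.0421). Gp2, a membrane glycoprotein of pancreatic zymogen granules and of the epithelium over lymphoid follicles, rose 11.7-fold (3.55 ± 0.86). S100a8 and S100a9, the subunits of calprotectin, an abundant protein of neutrophils, rose 13.6-fold (3.76 ± 1.104) and 11.4-fold (3.51 ± 0.76). Cstdc5 and Stfa1, inhibitors of cysteine proteases, rose 7.25-fold and 6.35-fold, the surface protein gene Ly6d rose 6.72-fold, and the resistin-like goblet cell gene Retnlb rose 6.14-fold (2.62 ± 0.93, adjusted p = 0.0451). Reg2, Reg3b, Reg3g and Gp2 were saturated in 2 of 4 mutants, so their folds are understated. Larger rises were given by Agilent's processed signals for Retnlb (16.5-fold, and 9.27-fold with a normexp offset of 10), Stfa1 (13.6-fold), S100a8 (24.8-fold) and Cstdc5 (11.8-fold). Probes of near-identical family members (Reg3, stefin A and Cyp4a genes) may share signal, and their values are uncertain in that respect. The pancreatic acinar list, whose cells can express Reg genes and Gp2, had medians of 0.15, 1.42, 1.32 and 0.85 on arrays 1 to 4 over the 8 to 10 members unsaturated there.

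After Cck, Gip and Nts, the largest falls were those of Cyp4a31 (4.16-fold, -2.06 ± 1.05) and Cyp4a10 (3.60-fold, -1.85 ± 1.07), fatty acid hydroxylases of the cytochrome P450 family. Both were lower by more on arrays 1 and 2 (-2.46 and -3.35 for Cyp4a31, -2.60 and -2.93 for Cyp4a10) than on arrays 3 and 4 (-1.31 and -1.102, -1.01 and -0.86). Gdf9, a growth factor known from oocytes, fell 3.29-fold (-1.72 ± 0.35), and ND4, a mitochondrially encoded subunit of respiratory complex I, fell 3.24-fold (-1.70 ± 0.73). The cell cycle transcription factor E2f8 fell 2.93-fold (-1.55 ± 0.38), the GABA-degrading enzyme Abat 2.88-fold (-1.53 ± 0.078), the muscle LIM protein gene Csrp3 2.86-fold, the urea cycle enzyme Otc 2.79-fold and Il1rl1, a receptor of the interleukin-1 family, 2.77-fold. Limma's adjusted p for these 9 falls lay between 0.0252 and 0.0485. Csrp3 was 5.42-fold lower with Agilent's processed signals and no longer past the threshold (adjusted p = 0.0616), and Il1rl1 fell 1.83-fold as the mean of its probes.

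**Figure D2:**
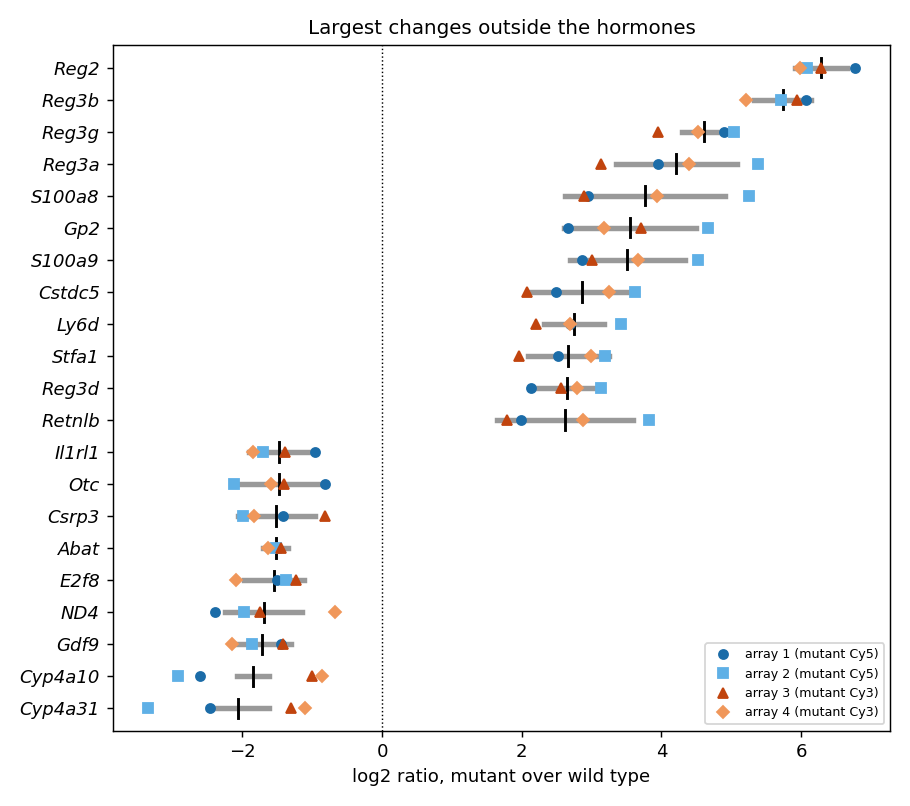
Log2 ratio of mutant over wild type for the 12 largest rises and the 9 largest falls outside the hormones. Points are the 4 arrays, black ticks the mean and grey bars the 95% confidence interval from limma, which leaves out differences between dye orientations. Reg2 lies between 5.98 and 6.77 and Abat between -1.63 and -1.45.

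Among epithelial cell types, the Paneth cell and antimicrobial genes included 6 of 9 tested members that rose and 1 that fell (7 and 1 adjusted over the list alone). Reg3g, Reg3b and Reg3a led it, and Itln1, a lectin of secretory cells, rose 3.09-fold (1.63 ± 0.40, adjusted p = 0.0421). The Paneth cell genes Mptx2, Defa24, Defa-rs1 and Defcr-rs1 had no probe under these symbols. Reg genes are also expressed in the pancreas, so a rise of this list does not show more Paneth cells. The list shifted up in camera (adjusted p = 9.23e-05; adjusted p = 0.521 with an estimated correlation). Of 10 readable goblet cell genes, 4 rose and none fell (6 and 0 adjusted over the list alone), and the list shifted up (adjusted p = 0.00266; adjusted p = 0.521 with an estimated correlation). Its medians were -0.01 and 0.28 on arrays 1 and 2 and 0.77 and 0.79 on arrays 3 and 4, which is also the order of the stomach list (-0.83 and -0.46, 2.77 and 3.37). The goblet gene Agr2, chosen after its values were seen, had -1.24, -0.75, 1.34 and 1.06 on arrays 1 to 4. The mucin Muc2 rose 1.59-fold (0.67 ± 0.13), the lectin Zg16 rose 1.55-fold (0.63 ± 0.17, understated because 2 of 4 mutants were saturated) and Retnlb as given above. The goblet transcription factor Spdef passed the test with 0.57 ± 1.02, but its ratios were -0.45 and -0.15 on arrays 1 and 2 and 1.38 and 1.51 on arrays 3 and 4. None of 9 tested tuft cell genes passed over all genes (1 higher adjusted over the list alone, camera adjusted p = 0.189), and Ptgs1 had 0.58 ± 0.25 (adjusted p = 0.0557), Avil 0.30 ± 0.40 (adjusted p = 0.1) and Trpm5 0.28 ± 0.42 (adjusted p = 0.105). The medians of the tuft list, too, were lower on arrays 1 and 2 (-0.12 and -0.19) than on arrays 3 and 4 (0.46 and 0.44).

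The Wnt target Lgr5, a marker of intestinal stem cells, fell 1.69-fold (-0.76 ± 0.29, adjusted p = 0.0421). It was the 1 stem cell gene of 12 past the threshold (1 higher and 4 lower adjusted over the list alone). Axin2, another Wnt target, had -0.46 ± 0.12 (adjusted p = 0.052), while Lrig1 had 0.43 ± 0.39 (adjusted p = 0.0565). The list was not past the threshold (camera adjusted p = 0.0943). None of 19 proliferation genes passed over all genes, and 7 were lower adjusted over the list alone. Of the 19, 18 had negative means, and the list shifted down (adjusted p = 0.000143; adjusted p = 0.575 with an estimated correlation). Mki67 had -0.80 ± 0.29 (adjusted p = 0.0526), Mcm6 -0.76 ± 0.29 (adjusted p = 0.0531) and Ccnb1 -0.59 ± 0.23 (adjusted p = 0.0522).

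Of 18 enterocyte genes of digestion and the brush border, 3 fell and none rose (9 and 0 adjusted over the list alone), and the list shifted down (adjusted p = 0.000972; adjusted p = 0.521 with an estimated correlation). The cadherin Cdh17 fell 1.73-fold (-0.79 ± 0.047), enteropeptidase, Tmprss15, 1.56-fold (-0.64 ± 0.086) and the glucose transporter Slc2a2 1.75-fold (-0.80 ± 0.25). Of 18 readable lipid absorption genes, 4 fell and none rose (1 higher and 4 lower adjusted over the list alone). Mttp, which loads lipid onto apolipoprotein B, fell 2.10-fold (-1.07 ± 0.19), Fabp1 fell 2.68-fold (-1.42 ± 0.32, understated because 3 of 4 wild types were saturated), Acsl5 2.63-fold (-1.39 ± 0.48) and Sar1b 1.52-fold (-0.61 ± 0.35). That list was not past the threshold (camera adjusted p = 0.102).

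Of 18 genes of fatty acid oxidation and ketogenesis, 8 fell and none rose (9 and 0 adjusted over the list alone), and the list shifted down (adjusted p = 9.23e-05; adjusted p = 0.536 with an estimated correlation). Besides Cyp4a10, Hadhb fell 1.71-fold (-0.77 ± 0.28), Cpt2 1.52-fold (-0.61 ± 0.18) and Ehhadh 1.78-fold (-0.83 ± 0.34), all enzymes of beta-oxidation or the carnitine shuttle. Its medians were -0.88, -0.50, -0.38 and 0.05 on arrays 1 to 4. Of 12 genes typical of the suckling epithelium, 1 fell (2 lower adjusted over the list alone): Cpt1a, which lets fatty acids into mitochondria, by 0.52 on the log2 scale. The NADPH oxidase gene Nox4 was not well above background in any mutant and was at least 1.39-fold lower (adjusted p = 0.052). With Agilent's processed signals it passed the threshold (adjusted p = 0.0418), but the size of the fall is not readable there either. The list shifted down (adjusted p = 0.00518; adjusted p = 0.521 with an estimated correlation). None of 20 cholesterol synthesis genes passed, over all genes or adjusted over the list alone, and Sc5d came closest (-0.57 ± 0.22, adjusted p = 0.054). The list shifted down (adjusted p = 0.0268; adjusted p = 0.644 with an estimated correlation), with medians of 0.06 and 0.07 on arrays 1 and 3 and of -0.69 and -0.51 on arrays 2 and 4. The call ended without array 2 (adjusted p = 0.362), without array 4 (adjusted p = 0.15) and with median centring (adjusted p = 0.0513). Without both arrays and without the dye term the direction turned (adjusted p = 0.516, upward).

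Markers of neighbouring organs, which a dissected duodenum can carry, differed between arrays. None of 19 readable pancreatic acinar genes passed over all genes, but all 19 had positive means and 9 were higher adjusted over the list alone (camera adjusted p = 1.74e-05, upward; adjusted p = 0.521 with an estimated correlation). Amylase, Amy2a5, was saturated in all mutants and at least 2.40-fold higher (adjusted p = 0.052), Bhlha15 had 1.29 ± 0.59 (adjusted p = 0.0536) and Pnliprp2 1.96 ± 1.15 (adjusted p = 0.0789). Of 8 tested islet genes, 1 rose (5 higher adjusted over the list alone), amylin, Iapp, 4.28-fold (2.10 ± 1.30, adjusted p = 0.0421), and the list shifted up (adjusted p = 0.00729; adjusted p = 0.521 with an estimated correlation). Insulin 1, Ins1, had 2.44, 2.40, 1.49 and -0.98 on arrays 1 to 4. The stomach list shifted up (adjusted p = 0.000143; adjusted p = 0.521 with an estimated correlation), with 3 of 7 tested members past the threshold (6 adjusted over the list alone), but no member past the threshold had 1 sign on all arrays. Its medians were -0.83 and -0.46 on arrays 1 and 2 and 2.77 and 3.37 on arrays 3 and 4, over 4 or 5 unsaturated members. The gastric genes Gkn2, Muc6 and Pgc passed with 1.95 ± 2.85, 0.78 ± 2.35 and 0.87 ± 2.13. Gkn2 had 1.31 and was not called with Agilent's processed signals (adjusted p = 0.113), and the stomach list was no longer past the threshold without a dye term (adjusted p = 0.0788). The distal bowel list, with 4 tested members and none past the threshold, gave an adjusted p of 0.857. Its median was 0.04 and its mean -0.55, and the water channel Aqp8 had -0.28, -4.37, -0.57 and -4.63 on arrays 1 to 4, with 3 of 4 wild types saturated.

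Of 14 genes of enteric neurons and glia, 3 rose and none fell (6 and 0 adjusted over the list alone): peripherin, Prph (0.70 ± 0.14), Uchl1 (0.64 ± 0.12) and the neuronal tubulin Tubb3 (0.65 ± 0.27). The list shifted up (adjusted p = 0.00321; adjusted p = 0.521 with an estimated correlation). None of 12 fibroblast and matrix genes passed, over all genes or adjusted over the list alone. That list shifted down (adjusted p = 0.0436; adjusted p = 0.594 with an estimated correlation), with medians of -0.83 and -0.62 on arrays 2 and 4 against -0.11 and -0.14 on arrays 1 and 3, and fibronectin, Fn1, had -0.59 ± 0.25 (adjusted p = 0.0557). Its call ended without array 2 (adjusted p = 0.0957), without array 4 (adjusted p = 0.084) and without both arrays and the dye term (adjusted p = 0.278). It also ended with median centring (adjusted p = 0.0551) and with Agilent's processed signals (adjusted p = 0.057). None of 12 smooth muscle genes passed over all genes (2 lower adjusted over the list alone, camera adjusted p = 0.102), and Synpo2 had -0.82 ± 0.34 (adjusted p = 0.0528) and Myh11 -0.60 ± 0.40 (adjusted p = 0.0557). Of 10 endothelial genes, Emcn fell (-0.60 ± 0.45, adjusted p = 0.0472), 4 were lower adjusted over the list alone, and the list was not past the threshold (camera adjusted p = 0.102). Of 18 immune cell genes, 2 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.783, median -0.03, mean 0.25). S100a8 and S100a9 were the 2 that rose, and the mast cell protease Mcpt2 fell (-0.96 ± 0.82, adjusted p = 0.0421), with -1.38 and -1.89 on arrays 1 and 2 and -0.16 and -0.40 on arrays 3 and 4. No erythroid gene of 8 and no adipose or liver gene of 6 passed (0 and 1 lower adjusted over the list alone, camera adjusted p = 0.102 and 0.189). The globin gene Hbb-bt had -0.68 ± 0.88 (adjusted p = 0.251), Ttr -1.20 ± 0.54 (adjusted p = 0.0557), and Serpina1a, saturated in all wild types and in 1 mutant, has no readable ratio.

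All 13 interferon response genes had negative means, none passed over all genes and 8 were lower adjusted over the list alone. The list shifted down (adjusted p = 0.000143; adjusted p = 0.575 with an estimated correlation), with medians of -0.41, -1.42, -0.41 and -1.51 on arrays 1 to 4. Rsad2 had -1.29 ± 0.54 (adjusted p = 0.0528; -2.17 with Agilent's processed signals, adjusted p = 0.0729) and Oasl2 -1.51 ± 0.75 (adjusted p = 0.0585). Of 12 immediate early and heat shock genes, Ier3 rose (0.48 ± 0.29, adjusted p = 0.0454) and 5 were higher adjusted over the list alone. That list shifted up (adjusted p = 0.0351; adjusted p = 0.521 with an estimated correlation), and lost its call without array 1 (adjusted p = 0.0634). Fos had 0.77 ± 0.33 (adjusted p = 0.0521). Of 11 clock genes, Per1 rose 1.99-fold (0.99 ± 0.33, adjusted p = 0.0475), 6 were higher and 1 lower adjusted over the list alone, and Nr1d1 had 1.16 ± 0.81 (adjusted p = 0.0538, camera adjusted p = 0.0738 for the list). Of 12 genes of the unfolded protein and amino acid responses, the endoplasmic reticulum chaperone genes Dnajb9 (-0.86 ± 0.19) and Hspa5 (-0.44 ± 0.071) fell, with 1 higher and 3 lower adjusted over the list alone, and the list was not past the threshold (camera adjusted p = 0.847). Probes for Xist, Uty and Kdm5d were above background in 0 of 8 channels, so they could not check the balance of sexes. The Y-linked Eif2s3y was above background in 8 of 8 channels and had -0.05, -0.22, -0.43 and -0.51 on arrays 1 to 4. Ddx3y, also Y-linked, was above background in 3 of 8 channels and had 0.125, 0.287, -0.04 and 0.207.

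Of the 29 lists, 14 passed the threshold with the preset correlation, 7 higher and 7 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.521), and 1 list, the Paneth cell and antimicrobial genes, had an unadjusted p under 0.05 (p = 0.0432). Among the 14 lists the estimated correlation ran from -0.09 (Paneth cell and antimicrobial) to 0.92 (interferon), against the preset 0.01. It was also high for cholesterol synthesis (0.88) and proliferation (0.71). Where it is far above the preset, the p-value at the preset overstates the evidence for a shift. By fry 6 lists moved on balance in one direction and 18 changed in either direction.

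**Figure D3:**
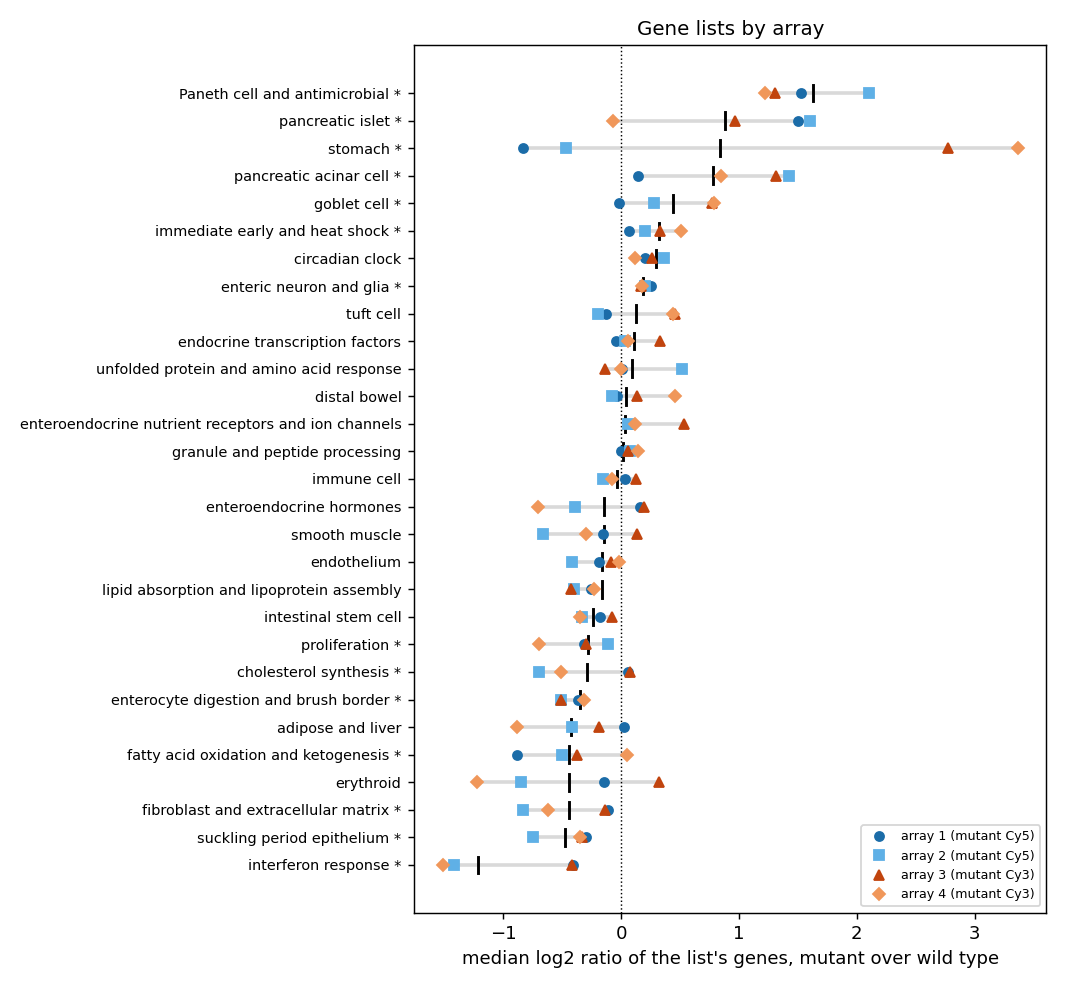
Median log2 ratio of mutant over wild type for the genes of each of 29 lists. Points are the 4 arrays, each leaving out spots saturated there, black ticks the median of the genes' means over the arrays, and an asterisk marks lists past the threshold in camera with the preset correlation (none with an estimated one). The Paneth cell and antimicrobial list lies between 1.22 and 2.11 on the 4 arrays, and the stomach list between -0.83 and 3.37.

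The authors' deposited table, made from the same arrays, holds 33352 probe values with a fold change, of which 486 pass its adjusted p at 0.05 (158 higher, 328 lower) and 3218 at 0.1. Across genes, its log2 fold changes correlated with those from the scanner files with r = 0.993. All 850 called genes had the same sign in the authors' deposited table, and 319 also passed its adjusted p. In the authors' deposited table the signed fold was -17.5 for Cck, -10.6 for Gip, -6.02 for Nts, 3.33 for Sst, -1.81 for Arx and 90.5 for Reg2.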

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

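The test of islet RNA, both tests on the Reg genes and the limit of the stomach tests to unsaturated values were chosen only after the result was seen, and the per-array ratios, though not the levels per animal, had been seen before the dye tests were written. For each named gene and list the 4 array ratios were searched for an array far from the others, as the gap to its nearest neighbour over the whole range. This was so for Hhex (0.888, array 4), Lamp2 (0.873, array 2), Slc4a1 (0.890, array 4) and the median of the nutrient receptor and ion channel list (0.877, array 3). These are 4 of 138 genes and 29 lists, and chance gives about 1 in 20. The dye orientations went opposite ways for Gkn2 (-2.465, the log2 distance of arrays 1 and 2 from the mean over both orientations) and for Muc6 (-2.03), with a dye coefficient past the threshold in limma.

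The stomach genes were higher in the mutant on arrays 3 and 4, and their median was lower on arrays 1 and 2. On array 2, however, Ctse and Tff1 were higher in the mutant. Their log2 levels were 11.33 and 14.31 in mutant 6 against 10.14 and 13.87 in wild type 2. A gene-specific dye bias would give the same gap between Cy3 and Cy5 samples in both genotypes: the median difference between the gaps was 0.663 with an SD of 3.92 over all 7 tested genes and 0.887 with an SD of 4.51 over the 4 unsaturated in all channels, so dye and animals cannot be told apart with 2 animals per dye and genotype. Gkn2 had gaps of opposite sign in the genotypes (6.86 and -1.93), and the other 3 had positive gaps in both. Mutants 7 and 8 were the 2 highest of 8 animals for 6 of the 7 tested genes, which met the limit of 6 set beforehand for stomach tissue in those samples, but wild types were saturated for 2 of the 6, and the 4 of 5 genes with a readable rank are too few to show or exclude it. No biological explanation through the genotype was tested.

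Gcg and the median of the islet genes were high in the mutant on arrays 1 and 2 and less so, or lower, on arrays 3 and 4. Among the islet genes, Mafa, Gcgr and Ucn3 were not clearly higher on both arrays 1 and 2. Their log2 levels on array 2 were 10.17, 8.99 and 7.52 in mutant 6 against 9.96, 9.09 and 7.82 in wild type 2. For dye bias the median difference of the gaps was -0.621 with an SD of 0.864 over 9 genes, and again dye and animals cannot be told apart with so few samples. Within a dye orientation, Gcg and the islet median ordered 2 of 2 pairs of arrays alike, which is too few to show or exclude unequal islet RNA in the samples of an array, and the pattern itself fixes the order of the other pairs. The difference between Gcg and the islet median was -0.40, -0.49, -1.47 and -1.87 on arrays 1 to 4. Whether intestinal Gcg changed with the genotype therefore stays open, in either direction.

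Reg2, Reg3a, Reg3b, Reg3d, Reg3g and Gp2 rose together. As far as the readable acinar genes show, more acinar tissue of unchanged makeup in the mutant samples is argued against as the whole source of this joint rise. The median of these genes exceeded that of the readable acinar members by at least 2.51 on every array. The SD over the acinar members was at most 0.727. The 6 genes were picked for their large rises, which can widen this gap, and 8 to 10 acinar members were readable per array. Of the 21 tested acinar genes, 13 were saturated in some channel and were left out on those arrays. A larger rise of these brightest members could not be read, which can also widen the gap. On array 2 the highest acinar member reached 3.25, above Reg3d (3.14), so the test does not decide for Reg3d alone. A lower share of enterocytes would raise the other cell types alike, by about as much as the 6 genes. The highest median log2 ratio among 9 lists of such cells, without the 6 genes, was 0.963, between the limits of 0.5 and 1. It belonged to the Paneth cell and antimicrobial list, while the others lay from -0.44 (fibroblast) to 0.44 (goblet). The median of the 6 genes was 3.83 to 5.21 on the 4 arrays. By those limits the test was undecided. The gap between the 9 list medians and that of the 6 genes argues against a lower share as the whole source of the rise, and leaves open a part of it. A change of expression within pancreatic cells present in the samples, or in the epithelium, may underlie the rise, and neither was tested. Array signal shared between near-identical Reg3 genes was not tested.

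Turning the sign of some of the arrays gave 7 patterns that could be fitted, the real one included. The real comparison called 850 genes and the highest of the others 0 (1074 at an unadjusted p under 0.05, against 5932), and 1 of the 7 patterns was as large. For lists passed by camera the real value was 14 and the highest other 12, and again 1 of the 7 was as large. With 7 patterns a share under 0.05 cannot be reached. A turned pattern also moves part or all of any true genotype effect into the residual or the dye term. Fewer calls there are thus built in, and no conclusion is drawn from them.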

How the results depend on the processing

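Chosen after the data were seen were the fits on arrays 1 and 3 alone, without probes saturated in any channel, and without the pancreas and stomach genes. Every fit on arrays 1 and 3 alone also dropped the dye term, so its changes cannot be put down to the arrays alone. The called genes among Arx, the hormones and the largest changes numbered 26. In each of the 16 planned settings with 4 arrays in which they were tested, all 26 kept their direction. Of the 26, 22 stayed past the threshold there. All 26 had the same sign on all 4 arrays, and the largest changes were picked for it. A kept direction on the same arrays is thus largely built in, and no conclusion is drawn from it. Aquantile and the looser threshold of 0.1 left every ratio as in the main fit, so neither could lose a call. All 850 genes kept their sign in most of the 16 settings, with 849 of 850 for the mean of a gene's probes and 815 of 816 still tested with all 8 channels above background. The kept sign is again largely built in, since 825 of the 850 had the same sign on all 4 arrays. Fewer of the 850 stayed called: 212 with Agilent's processed signals, 523 without a dye term, 570 for the mean of a gene's probes and 673 with median centring. At least 813 stayed called in each other setting with 4 arrays. The cause of the shifts below was not tested, except that leaving out an array leaves 1 residual degree of freedom. Arx ranged from -1.78 with Agilent's processed signals to -0.60 without array 1, with -0.81 without background correction and -1.06 with an offset of 10, and it was not tested where all 8 channels had to be above background.

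Genes past the threshold (higher, lower) numbered 276 (135, 141) with Agilent's processed signals, 1915 (1671 lower) with median centring and 1617 (659, 958) with scaling between arrays. They numbered 5717 (2706, 3011) in a separate-channel fit and 3841 (1739, 2102) at an adjusted p of 0.1. With arrays 1 and 3 alone and no dye term they numbered 57 (38, 19), and 545 were higher with an offset of 10. The share of calls that were higher was 38.7% in the main setting, 12.7% with median centring, which moved the median of all genes to -0.14, and 48.9% with Agilent's processed signals. Leaving out each array in turn gave 3 to 14 genes, 2 to 10 higher and 1 to 4 lower. The Arx ratio was then -0.80 to -0.60 (adjusted p 0.0804 to 0.268), and -0.79 with arrays 1 and 3 alone (adjusted p 0.105), past the threshold in none of these. The calls were 832 without saturated probes and 848 without the pancreas and stomach genes. Scaling by Aquantile leaves ratios within arrays as they are, so it moved nothing.

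Lists past the threshold were 0 with an estimated correlation, 6 by fry and 12 to 19 under the other settings. The hormone list passed by fry (0.0291) and its mixed form (0.00063), against camera values of 0.0579 to 0.644. The direction turned, with log2 ratios, for Insm1 (-0.0218) and Slc51b (-0.0525) with median centring, and with arrays 1 and 3 alone for Gcg (0.29), Tph1 (0.0532), Insl5 (0.18), Hbb-bt (0.00676), Hba-a1 (0.0665) and Hbb-b2 (0.12). Without 1 array, ranges took both signs for Slc51a (-0.30 to 0.10), Gast (-0.39 to 0.0815), Gcg (-0.41 to 0.30) and Tph1 (-0.27 to 0.0059). Lists that turned, by adjusted p, were distal bowel (0.989 with no dye term, 0.762 with all probes, 0.419 with arrays 1 and 3), cholesterol synthesis (0.516), erythroid (0.341), smooth muscle (0.72) and the unfolded protein response (0.427) with arrays 1 and 3, and the last by fry (0.447). Without 1 array, lists of both directions had adjusted p of 0.257 to 0.827 (immune cell), 0.201 to 0.873 (unfolded protein response) and 0.493 to 0.968 (distal bowel). Camera calls were also lost by the stomach list with no dye term (0.0788), and with arrays 1 and 3 alone, likewise without a dye term (0.0512). The fibroblast list lost its call without array 2 or 4, with median centring, with Agilent's processed signals and with arrays 1 and 3 alone (0.0551 to 0.278). The cholesterol list lost its call without array 2 or 4 and with median centring (0.0513 to 0.362), and the immediate early list without array 1 (0.0634). The authors' processed values per array were not run, since their columns could not be tied to samples, and Arx has no further probe to try.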

Other observations

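Several genes and lists had like ratios on arrays 2 and 4, whose animals differ in dye orientation, and other values on arrays 1 and 3. These were noted after the ratios were seen, and no test of an explanation was run. Aqp8, a water channel abundant in the large bowel, had -4.37 and -4.63 on arrays 2 and 4 against -0.28 and -0.57 on arrays 1 and 3, and the colonic hormone Insl5 had -2.28 and -2.43 against 0.16 and 0.21. Aqp8 was saturated in 3 of 4 wild types. The other tested distal bowel genes were not lower on both arrays 2 and 4. There Car1 had -0.08 and 0.46, Slc51a 0.30 and 0.13, and Slc51b -0.23 and 0.85. Among the other hormones, Pyy had 0.008 and -0.08 on arrays 2 and 4 against 0.82 and 1.14 on arrays 1 and 3. Sct had -1.27 and -1.16 against -0.47 and -0.48. The median of the erythroid list was -0.85 and -1.22 against -0.14 and 0.32, and that of the interferon list -1.42 and -1.51 against -0.41 and -0.41. Across genes, arrays 2 and 4 also had the highest Pearson correlation of any pair (r = 0.651), but by rank (Spearman's rho 0.506) they came after arrays 3 and 4 (r = 0.625, rho 0.632) and arrays 1 and 2 (r = 0.556, rho 0.549), the pairs that share a dye orientation.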
